A study of Homo sapiens with 6 samples.

How the data were processed

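Total RNA of Hep3B cells was sequenced on a BGISEQ-500 after 6 hours with 1 µM FIIN-2 or with DMSO, 3 libraries each. The deposited files hold whole-number read counts per gene and, separately, FPKM values per gene, per the file headers. The counts were deposited without normalization. The FPKM values were scaled by the authors to transcript length and library total and rounded to 2 decimals. Per the submitters' processing notes, HISAT, DESeq2 and the build GRCh38 were used. The role and version of each tool, the read counter, the annotation, strandedness and trimming are not given in the sources used here. Over all libraries 41 counts of 0 stand beside an FPKM above 0, so the counts may be rounded from fractional estimates, which would divide reads between near-identical genes by a model. Reads of overlapping or antisense genes cannot be told apart, since no source says that strand was used.

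The count table holds 18234 genes by Entrez ID and symbol, 733 of them with no read in any library. Of the IDs, 17958 matched the RefSeq gene table of assembly GRCh38.p14, from which the gene coordinates (1-based) were taken. Mitochondrially encoded genes, fixed as 1 list, had no row in the table, so 33 of 34 lists were tested. Every column of per-sample values was matched to its library by name. Totals per library were 14552868, 15494402 and 15583410 counts for DMSO and 15181678, 14839073 and 15035859 for FIIN-2.

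The main test was edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (a count minimum of 10, a total minimum of 15), libraries were scaled by TMM, and the quasi-likelihood F test compared FIIN-2 with DMSO with no covariate. Benjamini-Hochberg adjustment ran over the 13793 tested genes, and genes with adjusted p under 0.05 were called. Values are CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries, and log2 fold changes ± the standard error that the F statistic implies. A fold against a group with 0 counts was computed from 3 counts over that group. It leaves out the counting error of the other group, so it is not a strict lower bound. The gene lists were tested with camera (limma 3.58.1) on the edgeR fit, with its preset correlation of 0.01, for lists with at least 3 tested members, and adjusted over the 33 lists. The median log2 fold change of all tested genes was 0.0026 under TMM.

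The test, the lists, the alternatives and the rule for named genes were chosen before the data were examined. Named are the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 5 CPM and no overlap between the groups, the FGF receptors, KLB, FGF19 and CYP7A1, up to 4 called members with the smallest p in the direction of each shifted list and up to 2 in the other direction, and up to 2 called members of each other list. Some lists are given by count alone, and a few genes that the rule names are not reported here. Genes outside the rule are said to be so.

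Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter beyond 1 read, a filter of 1 CPM in 3 libraries, the replicate number as a block, limma on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, limma on log2(FPKM + 1) for all genes, an adjusted p under 0.01, and each library left out in turn. For the lists an estimated correlation and fry were added. Alternatives chosen after seeing the data were edgeR's glmTreat against 1.2-fold, an assumed coefficient of variation of 10% or 20%, offsets from a loess fit on GC content and length of each gene's longest GENCODE v29 transcript (98.5% of tested genes had one), and leaving out the MTRNR2L genes. The fits with an assumed variation used edgeR's likelihood ratio test in place of the quasi-likelihood F test.

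The tests were checked on counts simulated for the 13793 genes with the means, library sizes and dispersion of these 6 libraries. Of 50 genes changed by 2-fold, edgeR recovered 49, of 50 changed by 1.5-fold 43, of 50 changed by 1.2-fold 39, and of 50 changed by 1.1-fold 18. Among 13573 unchanged genes 11 were called, 6.36% of all calls. In the same simulation, where most genes were unchanged, camera called a list of 20 genes shifted by 1.2-fold and none of the other lists.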

Results

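RNA sequencing was carried out on Hep3B, a cell line from a human hepatocellular carcinoma, after 6 hours with 1 µM FIIN-2 or with its solvent DMSO. FIIN-2 is a covalent inhibitor of the fibroblast growth factor receptors, whose signal runs in large part through the kinase ERK. There were 3 libraries per group, read on a BGISEQ-500. Their totals ran from 14552868 to 15583410 counts, and CPM below are counts scaled to a common library total. The Poisson interval and the floor given for CYP7A1 cover counting error only. Across genes, which are not independent replicates, Pearson's r of log2 CPM was at least 0.9948 between libraries of one group and at most 0.9723 between libraries of different groups. Every pair of libraries within a group differed by more than Poisson counting noise, with a chi-square per degree of freedom of 1.32 to 1.48. None was counted as a repeat of another. The counts may be rounded estimates, however, so this excess cannot exclude libraries made from the same RNA. The labels do not say whether the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

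The single comparison of the design, FIIN-2 against DMSO, asks which transcripts the inhibitor moves within 6 hours. Transcripts that depend on ERK signalling fell together, as did targets of YAP, TGF-beta and NF-kappaB and genes of ribosome biogenesis, while genes of the differentiated hepatocyte rose. Of 13793 genes tested, 9016 (65.4%) were called at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 4476 higher and 4540 lower. Most changes were small. Of the called genes, 6586 moved by less than 1.5-fold and 998 by at least 2-fold, of which 630 were higher and 368 lower. At least 4-fold changes were found for 76 genes higher and 41 lower. The groups did not overlap for 9306 genes (67.5% of those tested, where chance gives 10%). The balance of the small calls depends on the scaling: edgeR with upper-quartile scaling called 5370 higher and 3691 lower, and with offsets for GC content and length, added after seeing the data, 4003 higher and 5051 lower. Limma on log2(FPKM + 1) of all genes, which differs in test and filter too, called 5196 higher and 3370 lower, and at least 2-fold changes on that scale, which understates changes of low genes, numbered 370. An alternative chosen after seeing the data assumed a coefficient of variation of 20% for every gene. The estimate common to all genes was 1.68%, and the median of the estimates per gene was 2.15%. With 20% assumed, edgeR's likelihood ratio test called 1730 genes, 962 of them at least 2-fold.

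**Figure D1:**
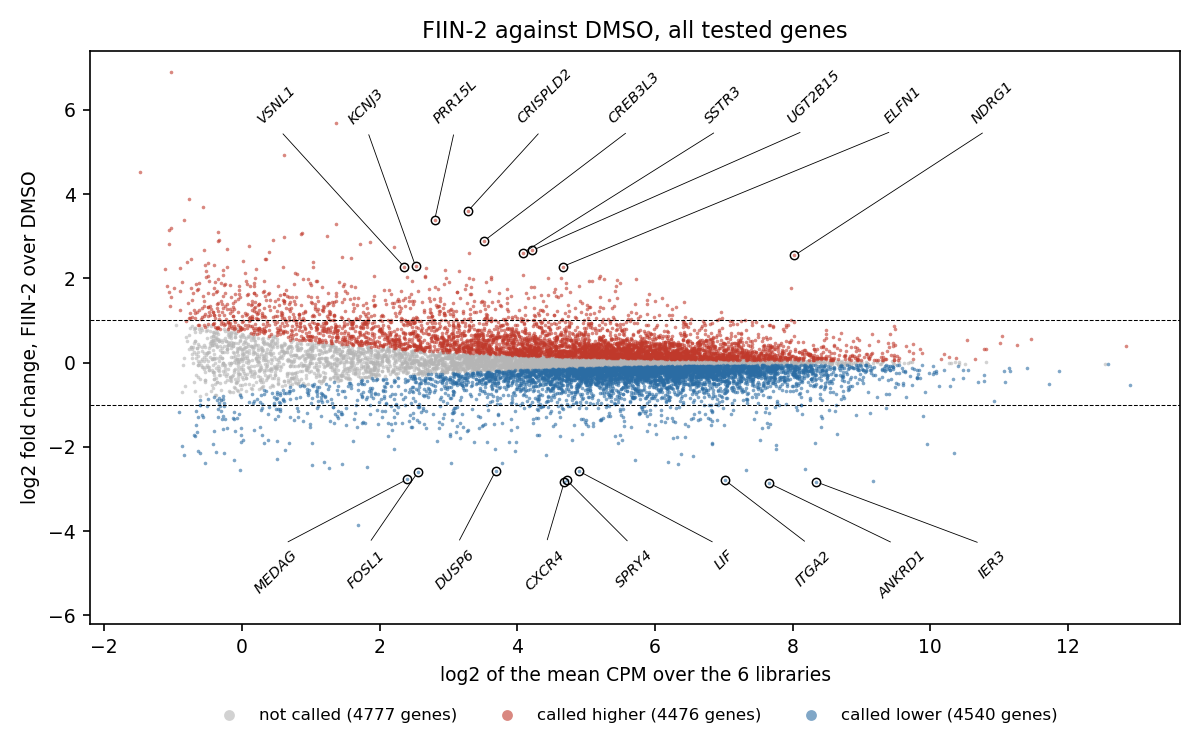
Log2 fold change of FIIN-2 over DMSO (y axis) against the log2 of the mean CPM over the 6 libraries (x axis) for the 13793 tested genes, each a point, with the 4476 genes called higher in red and the 4540 called lower in blue; dashed lines mark 2-fold. The circled genes are those named in the text from the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 5 CPM, and among the 998 called genes beyond the dashed lines 630 lie above and 368 below.

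The largest decreases included regulators of adhesion, matrix and cytokine signalling. ANKRD1, a cardiac ankyrin repeat protein known as a YAP target (Entrez 27063, chromosome 10, 90912096 to 90921087), went from 356 ± 4.71 to 48.8 ± 2.21 CPM (SD, n = 3 in each group), a log2 fold change of -2.87 ± 0.03 (SE). The chemokine receptor CXCR4 fell by 2.84 on the log2 scale, the integrin subunit ITGA2 by 2.79 and MEDAG by 2.77, and the cytokine LIF fell by 2.57. IER3, SPRY4, FOSL1 and DUSP6 are also among the largest decreases and belong to the ERK list below. The genes named here had adjusted p of at most 2.39e-16 in edgeR.

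The largest increases were mostly of weakly expressed transcripts, and genes with few reads tended to be higher as a whole (a median log2 fold change of 0.31 for genes with a mean of 10 to 30 reads). CRISPLD2, a secreted protein (Entrez 83716, chromosome 16, 84819985 to 84909508), went from 1.48 ± 0.03 to 17.9 ± 0.403 CPM, a log2 fold change of 3.59 ± 0.13. PRR15L rose by 3.38 and CREB3L3, a liver-enriched transcription factor (Entrez 84699, chromosome 19, 4153631 to 4173054), rose by 2.89. UGT2B15, which conjugates steroids and drugs with glucuronic acid, rose by 2.66, but its reads can be shared with close paralogs and its value is uncertain. The somatostatin receptor SSTR3 rose by 2.61, KCNJ3 and ELFN1 by 2.28 and VSNL1 by 2.27. NDRG1 was the most abundant of these (Entrez 10397, chromosome 8, 133237175 to 133297252) and went from 76.3 ± 0.887 to 445 ± 4.97 CPM, a log2 fold change of 2.54 ± 0.03. The genes named here had adjusted p of at most 8.49e-15 in edgeR.

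Transcripts of the FGF receptors changed by less than 1.5-fold. FGFR4 (Entrez 2264, chromosome 5, 177086915 to 177098144) had 242 ± 1.57 CPM in DMSO and 255 ± 1.28 CPM with FIIN-2, a log2 fold change of 0.07 ± 0.02 with adjusted p = 0.0080 in edgeR. With offsets for GC content and length, added after seeing the data, its log2 fold change was -0.09 (adjusted p = 0.000576 in edgeR), and over all its alternatives in edgeR, DESeq2 and limma adjusted p ranged from 1.21e-05 to 1, so its direction is not settled. FGFR3 rose by 0.41 ± 0.02, from 270 ± 4.69 to 360 ± 6.73 CPM. FGFR1 and FGFR2 were not called, with log2 fold changes of 0.01 ± 0.03 and 0.04 ± 0.04, although upper-quartile scaling in edgeR and 3 limma fits on FPKM called FGFR2 higher, with adjusted p of 0.0364 to 0.0430, against 0.155 to 1 in its other alternatives. KLB, the co-receptor beta-klotho, rose by 0.72 ± 0.05 (40.6 ± 2.17 to 67.1 ± 2.33 CPM), and FGF19, the ligand of FGFR4 with KLB, fell by 0.58 ± 0.13 (9.61 ± 1.81 to 6.43 ± 1.12 CPM, adjusted p = 0.000166 in edgeR). CYP7A1, the rate-limiting enzyme of bile acid synthesis, lay below the count filter. It had 0 counts in each DMSO library and 7, 3 and 5 counts in the FIIN-2 libraries, together 15 (95% exact Poisson interval 8.40 to 24.7). These 15 counts were 4.82-fold above a floor of 3 counts over the DMSO group. That fold leaves out the counting error of the 15, so it is not a strict lower bound. Without the filter the adjusted p of CYP7A1 was 0.000732 in edgeR, and over the fits that could test it adjusted p ranged to 0.00823 in limma on FPKM.

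The transcriptional output of ERK was lower throughout. All 19 tested genes of the list fell, with a median log2 fold change of -1.61 (camera on the edgeR fit, adjusted p = 2.62e-39). IER3, an early response gene, went from 568 ± 24.6 to 79.8 ± 5.97 CPM (log2 fold change -2.83 ± 0.03), SPRY4, a feedback inhibitor of receptor signalling, from 46.1 ± 0.531 to 6.64 ± 0.677 CPM (-2.79 ± 0.07), and the receptor EPHA2 from 136 ± 1.89 to 25.6 ± 1.34 CPM (-2.41 ± 0.04). FOSL1, an AP-1 subunit, fell by 2.59, and the ERK phosphatase DUSP6 fell by 2.56.

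**Figure D2:**
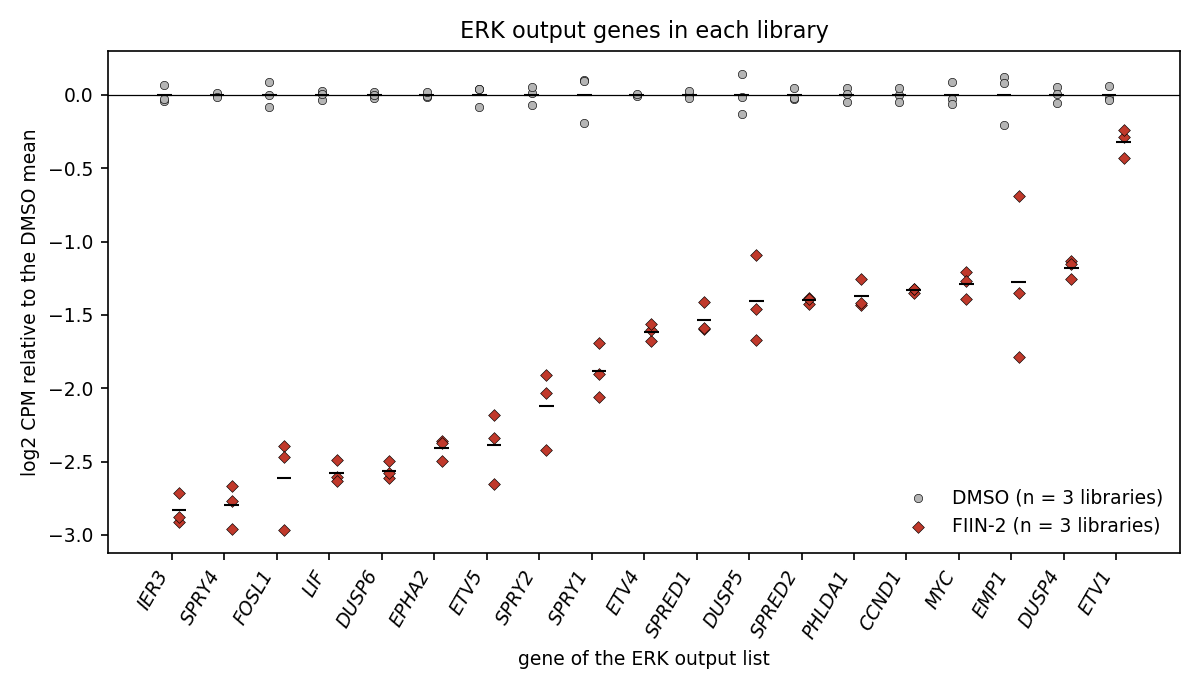
Log2 CPM of each of the 19 tested ERK output genes (x axis), relative to the gene's mean over the DMSO libraries (y axis), in the 3 DMSO libraries (grey circles) and the 3 FIIN-2 libraries (red diamonds), with the group mean as a bar. The FIIN-2 values lie between -2.96 and -0.24, the last in ETV1, and the DMSO values between -0.20 and 0.15.

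Immediate early genes and targets of 3 further pathways fell as well. Of 21 immediate early genes, 15 fell, 3 rose and 3 were not called, with a median of -0.65 (camera on the edgeR fit, adjusted p = 4.36e-11). JUNB fell by 1.22, and the matricellular genes CTGF and CYR61 by 1.92 and 1.49, while BTG2, an antiproliferative gene, and the orphan receptor NR4A2 rose by 1.05 and 1.17. The third that rose, NR4A3, was named after its value was seen. Of 21 YAP/TEAD targets, 18 fell and 2 rose, with a median of -0.67 (adjusted p = 3.05e-23 by camera). CTGF, CYR61 and ANKRD1 are on that list too, CRIM1 fell by 0.95, and ARHGEF17 and MYOF rose by 0.47 and 0.19. Of 19 TGF-beta and SMAD targets, 17 fell and 2 rose, with a median of -0.56 (adjusted p = 4.12e-17 by camera). ID1 fell by 1.78, SMAD6 by 1.31 and SKIL by 0.90, and INHBE and TGFBI rose by 0.35 and 0.19. Of 19 NF-kappaB targets and chemokines, 15 fell and 4 were not called, with a median of -0.75 (adjusted p = 2.64e-12 by camera). The chemokines CXCL8 and CCL20 fell by 1.94 and 1.80, the adhesion molecule ICAM1 by 1.83, from 289 ± 5.36 to 81.0 ± 2.87 CPM, and BIRC3, an inhibitor of apoptosis, by 1.46.

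Genes of ribosome biogenesis fell as a set, and the list of ribosomal proteins was not shifted. In the list of ribosome biogenesis and nucleotide synthesis, 30 of 32 genes fell and none rose, with a median of -0.59 (camera on the edgeR fit, adjusted p = 6.92e-16). ODC1, the first enzyme of polyamine synthesis, fell by 1.34, UTP20 by 0.94, MYBBP1A by 0.92 and NOLC1 by 0.72. Of 36 cytosolic ribosomal proteins, 3 rose, 13 fell and 20 were not called, with a median of -0.02 (adjusted p = 0.777 by camera). Of 30 genes of the G1/S transition and DNA replication, 5 rose and 12 fell, with a median of -0.04 (adjusted p = 0.613 by camera), among them RRM2 with -0.32 and MCM7 with -0.26. Of 30 genes of G2/M phase and mitosis, 10 rose and 8 fell (adjusted p = 0.830 by camera), with NUSAP1 at 0.37 and ECT2 at -0.37. Fry, which asks only whether members move one way on balance, called the G1/S list lower (adjusted p = 0.000260). It did not call the ribosomal proteins or the G2/M genes (adjusted p = 0.127 and 0.534 by fry).

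Hepatocyte genes rose. Of 28 hepatocyte transcription factors and secreted proteins, 24 rose, 2 fell and 2 were not called, with a median of 0.54 (camera on the edgeR fit, adjusted p = 4.44e-15). Albumin (ALB) went from 2285 ± 12.6 to 3367 ± 69.2 CPM (log2 fold change 0.56 ± 0.02), the fibrinogen chains FGA and FGG rose by 1.69 and 1.82, and the transcription factor ONECUT1 rose by 1.12. The transcription factor PROX1 fell by 0.31. Of 30 genes of hepatocyte drug, amino acid and urea metabolism, only 18 passed the count filter. Of these 18, 15 rose and 3 fell, with a median of 0.86 (adjusted p = 1.96e-08 by camera). Genes with few reads were higher as a whole (median 0.31 at a mean of 10 to 30 reads). Camera compared the list with all other tested genes, not with genes of like abundance, so the share of that trend was not tested. CYP3A7, a fetal cytochrome P450, rose by 2.02, from 14.4 ± 0.912 to 58.4 ± 2.31 CPM, and the urea cycle enzyme ASS1 by 0.93. CYP2B6 and ASL fell by 0.77 and 0.25. The third that fell was UGT1A1, named after its value was seen.

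The acute phase and bile acid lists also shifted higher, and both lost the call with an estimated correlation. They too were not compared with genes of like abundance, so the share of the trend of genes with few reads was not tested. Of 23 acute phase genes, 17 passed the count filter. Of these 17, 12 rose and 3 fell, with a median of 0.81 (camera on the edgeR fit, adjusted p = 5.84e-05, and adjusted p = 0.0691 with an estimated correlation). FGA and FGG are among them, IL6R, the interleukin-6 receptor, rose by 1.21 and C3 by 0.31, and CP (ceruloplasmin) and the feedback inhibitor SOCS3 fell by 0.16 and 0.66. The third that fell, STAT3, was named after its value was seen. Of 21 genes of bile acid synthesis and transport, 15 passed the count filter. Of these 15, 9 rose, 1 fell and 5 were not called, with a median of 0.43 (adjusted p = 0.000850 by camera, and adjusted p = 0.0656 with an estimated correlation), or 0.93 without the count filter. NR1H4, the bile acid receptor FXR, rose by 1.72, BAAT, which conjugates bile acids, by 0.98 and the nuclear receptor NR5A2 by 0.97. The one that fell was NR0B2, the repressor SHP and itself a target of FXR, from 22.9 ± 1.03 to 12.2 ± 0.383 CPM (-0.91 ± 0.08).

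Among genes that FOXO factors induce when AKT is inactive, 13 of 20 rose and 5 fell, with a median of 0.38 (camera on the edgeR fit, adjusted p = 0.00188, and adjusted p = 0.0684 with an estimated correlation). SESN3 rose by 1.54, CCNG2 by 1.08, ERBB3 by 0.90 and IRS1 by 0.84, while IRS2 and GADD45A fell by 0.49 and 0.78. Of 19 other receptor tyrosine kinases and ERBB ligands, 13 fell and 5 rose, with a median of -0.35 (adjusted p = 0.0314 by camera, adjusted p = 0.328 with an estimated correlation, adjusted p = 0.0689 by camera without FIIN-2 replicate 1, and 0.000378 to 0.328 over all alternatives). The ligands EREG and AREG fell by 1.91 and 1.33, and the receptors MET and PDGFRA by 1.07 and 1.06. ERBB3, from 171 ± 3.48 to 319 ± 7.79 CPM, and IGF2 went the other way, with 0.90 and 0.47.

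Of 21 BCL2 family members and apoptosis regulators, 11 fell and 4 rose, with a median of -0.29 (camera on the edgeR fit, adjusted p = 0.00412, and adjusted p = 0.0715 with an estimated correlation). The antiapoptotic BCL2L1 (BCL-XL) went from 611 ± 5.89 to 189 ± 1.08 CPM (-1.69 ± 0.02), MCL1 fell by 0.76 and BIRC2 by 0.74, and the proapoptotic BMF and BCL2L11 (BIM) rose by 0.69 and 0.39. The other two that rose, BAD and BIK, are proapoptotic as well, but proapoptotic members were also among those that fell, such as the death receptors TNFRSF10A and TNFRSF10B; these genes were named after their values were seen, and no split by role was tested.

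Of 31 genes of the ATF4 amino acid response, 20 fell and 5 rose, with a median of -0.20 (camera on the edgeR fit, adjusted p = 0.000289, and adjusted p = 0.108 with an estimated correlation). TRIB3 fell by 1.27, and the amino acid transporters SLC7A1 and SLC38A2 by 1.16 and 0.86, while NUPR1 and PSPH rose by 0.96 and 0.90. Of 29 genes of glycolysis and the hypoxia response, 17 fell and 6 rose, with a median of -0.22 (adjusted p = 0.0266 by camera, and adjusted p = 0.108 with an estimated correlation). The median was -0.130 without DMSO replicate 2 and -0.316 without FIIN-2 replicate 3, the ends of its range over the fits that leave out 1 library, and the list was called in each of these. EGLN3 fell by 1.52, the hexokinase HK2 by 1.02 and LDHA by 0.75. NDRG1, on the same list, rose as given above, and VEGFA rose by 0.17.

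Of the 33 lists tested, 5 were shifted higher and 10 lower with the preset correlation of camera, 2 and 6 with an estimated correlation. The 8 that held were the ERK output, immediate early, ribosome biogenesis, NF-kappaB, YAP/TEAD and TGF-beta lists, all lower, and both hepatocyte lists, higher. Counts adjusted over the list alone were the same as those given for 27 lists. They differed for the YAP/TEAD targets (2 higher and 19 lower), the acute phase genes (13 and 4), the ribosomal proteins (1 and 12), the G2/M genes (9 and 8), the interferon-stimulated genes (10 and 1) and the cholangiocyte and progenitor markers (5 and 5).

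**Figure D3:**
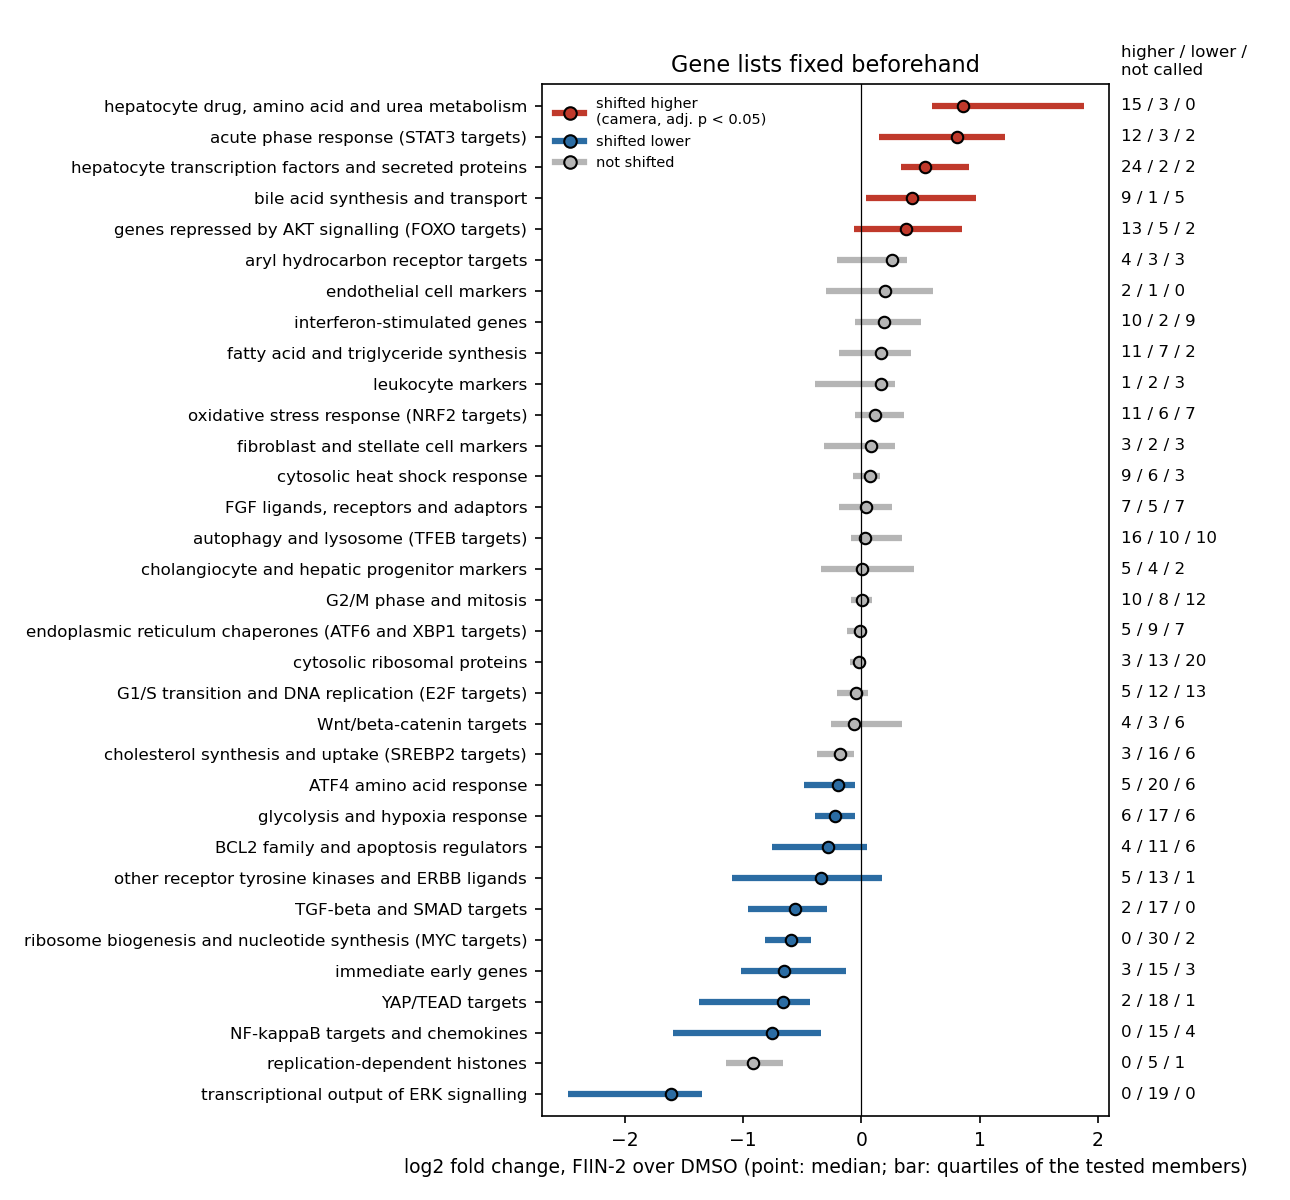
Median log2 fold change of FIIN-2 over DMSO (points, x axis) and quartiles (bars) of the tested members of each of the 33 gene lists (y axis), red where the list was shifted higher and blue where it was shifted lower by camera at an adjusted p under 0.05. Numbers at the right count the members called higher, called lower and not called; the ERK output list, at -1.61, lies lowest and the list of hepatocyte metabolism, at 0.86, highest.

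Camera called none of the lists of other metabolic and stress programmes below as shifted, though single members were called. Fry, which asks only whether members move one way on balance, called most of them. It called the cholesterol, FGF and Wnt lists lower (adjusted p = 0.000250, 0.00942 and 0.0144 by fry). The fatty acid, heat shock and interferon lists were higher (adjusted p = 0.00102, 0.00699 and 0.000247 by fry). Of 25 genes of cholesterol synthesis and uptake, 16 fell and 3 rose (median -0.19, adjusted p = 0.118 by camera on the edgeR fit), with TM7SF2 among the 3 at 0.95. Of 20 genes of fatty acid and triglyceride synthesis, 11 rose and 7 fell (adjusted p = 0.331), with MLXIPL at 1.36 and ACSL3 at -0.56. The 19 FGF ligands, receptors and adaptors had 7 higher and 5 lower, a median of 0.04 and a test that pointed lower (adjusted p = 0.868), with the adaptor SHC1 at -0.85 and the phosphatase PTPN11 at -0.47. The FGF median ran from 0.0120 (without FIIN-2 replicate 3) to 0.0536 (without DMSO replicate 3) over the fits that leave out 1 library. The 21 endoplasmic reticulum chaperones had 5 higher and 9 lower, a median of -0.01 and a test that pointed higher (adjusted p = 0.777), with SEL1L at 0.58 and XBP1 at 0.40. Of 18 heat shock genes, 9 rose and 6 fell (adjusted p = 0.590), with DNAJB1 at -0.65 and HSPA1B, which shares reads with HSPA1A, at 0.84. Of 21 interferon-stimulated genes, 10 rose and 2 fell (adjusted p = 0.301), with STAT2 at 0.59 and MX1 at 0.68. Of 13 Wnt targets, 4 rose and 3 fell (adjusted p = 0.889), with DKK1 at -1.53 and GLUL at 0.76. In edgeR each gene given a value here had an adjusted p under 0.05.

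Markers of other cell types were mostly below the filter or moved in both directions. Of 14 fibroblast and stellate cell markers 8 were tested, with 3 higher and 2 lower, of 12 endothelial markers 3, with 2 higher and 1 lower, and of 15 leukocyte markers 6, with 1 higher and 2 lower. Camera on the edgeR fit gave adjusted p of 0.889, 0.889 and 0.952. Fry called the fibroblast and endothelial lists lower (adjusted p = 0.0278 and 0.0493) and did not call the leukocyte list (adjusted p = 0.532 by fry). It called the cholangiocyte and progenitor markers given below higher (adjusted p = 0.000216 by fry). Camera pointed lower for the fibroblast and endothelial lists, whose medians were 0.08 and 0.20, and higher for the leukocyte list, whose mean was -0.03 and median 0.16. None of these directions is settled: without DMSO replicate 3 the leukocyte median was 0.0128 and camera pointed lower, and without the count filter the fibroblast, endothelial and leukocyte medians were -0.0188, -1.35 and 0.284. COL1A2 had a log2 fold change of 0.26, ESAM -0.80, PECAM1 1.01, LYZ -0.80 and CD68 0.29. Of 11 cholangiocyte and hepatic progenitor markers, 5 rose and 4 fell (adjusted p = 0.196 by camera on the edgeR fit), with SOX9 at -1.32, from 134 ± 4.40 to 53.4 ± 2.10 CPM, and CD24, whose reads can be shared with copies elsewhere, at 0.63. Of 6 replication-dependent histone genes tested, a list that follows poly(A) selection and RNA quality as well as the cell cycle, 5 fell (median -0.92, adjusted p = 0.0887 by camera on the edgeR fit, and median -0.487 with adjusted p = 0.302 without the count filter, over all alternatives 4.70e-05 to 0.302), with HIST1H2BK going from 37.4 ± 1.55 to 18.7 ± 0.251 CPM and HIST2H2BE from 8.21 ± 0.595 to 2.82 ± 0.135 CPM, both from families of near-identical copies.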

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

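The glmTreat fit, the assumed variation, the GC and length offsets and the fit without MTRNR2L genes were chosen after seeing the data. The 9016 calls stayed within 1.5 times under every alternative chosen before, from 7382 (DESeq2) to 9215 (no filter). The at least 2-fold calls were 370 with limma on log2(FPKM + 1), with and without the filter, where the pseudocount shrinks low genes. The calls fell to 4071 (2176 higher, 1895 lower) with glmTreat against 1.2-fold, which asks for a larger change, to 4809 (2576 and 2233) with an assumed variation of 10% and to 1730 (1012 and 718) with 20%, which replace the spread between libraries; the at least 2-fold calls were 962 or more in these fits. Leaving out 1 library gave 8487 to 8663 calls and 1050 to 1092 of at least 2-fold. No pairing by replicate number was seen: correlations of same-numbered deviations were -0.014, -0.00094 and 0.029 over 7004 genes, and not every library correlated best with its own number. With so few libraries and so small a spread, these values cannot show that same-numbered libraries were handled apart. The fit with the replicate block called 9037 genes (4481 higher, 4556 lower, 1001 at least 2-fold), with 5 lists higher and 10 lower.

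With an estimated correlation, 2 lists were shifted higher and 6 lower. For the bile acid, FOXO, apoptosis and glycolysis lists, which lost the call, the estimate was -0.029, -0.020, -0.038 and -0.015. These lie below the preset 0.01, so a higher correlation cannot explain the loss there. In the simulated counts, drawn for each gene independently, the list shifted by 1.2-fold had adjusted p = 6.9e-27 by camera with the preset. With an estimated correlation it had adjusted p = 0.00927 by camera. The estimated setting thus gave a larger p without correlation between genes, so a lost call does not show that members were correlated. The estimate lay above the preset in the acute phase (0.043), ATF4 (0.044) and receptor tyrosine kinase (0.093) lists, and the cause was not tested further. With fry, which asks only whether members move one way on balance, 11 were higher and 18 lower. The median of the ERK list ran from -1.74 to -1.58 over 12 alternatives, with adjusted p of at most 0.00735 in camera and fry. Of the other lists, only the receptor tyrosine kinase list lost its call when 1 library was left out, FIIN-2 replicate 1. Medians of 4 uncalled lists changed sign when 1 library was left out, the Wnt list most, from -0.0639 to 0.0296 without DMSO replicate 1; the others lay within 0.03 of 0.

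Of 129 named genes, FGFR1 changed sign, uncalled, with log2 fold changes from -0.0244 to 0.0423 over the fits that leave out 1 library (negative without DMSO replicate 1 and without FIIN-2 replicate 3) and -0.0471 with GC and length offsets. FGFR4 was at -0.0946 with these offsets; the cause was not tested. Of 2707 values, 2636 kept direction and side of the threshold. FGFR2 gained a call in 4 fits. Of 63 lost calls, 2 were under alternatives chosen before (RPL6 and RPL4, limma on log2(FPKM + 1) of all genes) and 37 under an assumed variation of 20%; none followed from leaving out a library. Depth limits genes such as CYP7A1, with at most 7 counts in a library.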

Other observations

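The tests of the low-count genes, the MTRNR2L genes, the families and the transcript lengths, and that of random raised lists, were chosen only after their results were seen. The test of other splits and those of CYP7A1, NRF2, AHR and autophagy were chosen before the data were examined.

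Most tested keratin genes fell and most tested genes with UGT symbols rose. When genes were grouped by the letters their symbols share, 172 families had at least 10 tested members, and 7 were shifted at an adjusted p under 0.05 (camera on the edgeR fit, preset correlation), 3 higher and 4 lower; none was with an estimated correlation (lowest adjusted p = 0.117). The members named here were chosen after their values were seen. Of 12 keratins, 10 fell and none rose, with a median log2 fold change of -1.02 (adjusted p = 7.97e-22 by camera, and adjusted p = 0.117 with an estimated correlation). KRT8 and KRT18, the keratin pair of hepatocytes, went from 2542 to 1347 CPM and from 1346 to 554 CPM, KRT23 fell by 1.53 and KRT17 by 1.19, and KRT19 fell by 0.33. Of 12 UGT genes, 10 rose and 2 fell, with a median of 0.99 (adjusted p = 0.00104 by camera, and adjusted p = 0.693 with an estimated correlation). UGT2A3 rose by 1.04, UGT3A1 by 1.18 and UGT2B4 by 0.94, whereas UGT1A1 and UGT8 fell by 0.25 and 0.23; UGT genes share sequence, so single values are uncertain.

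Of 15 aldehyde dehydrogenases 11 rose and 1, ALDH9A1, fell (median 0.36, adjusted p = 0.00963 by camera on the edgeR fit, and 0.693 as adjusted p with an estimated correlation), with ALDH1A1 going from 523 to 908 CPM. Of 10 cadherins 7 rose and 1, CDH19, fell (median 0.48, adjusted p = 0.00709 by camera, and adjusted p = 0.693 with an estimated correlation), with E-cadherin (CDH1) and N-cadherin (CDH2) rising by 0.50 and 0.38. Of 53 genes with EIF symbols, which cover translation initiation factors and also kinases and binding proteins that inhibit initiation (EIF2AK and EIF4EBP genes), 37 fell and 7 rose (median -0.20, adjusted p = 0.00861 by camera, and adjusted p = 0.975 with an estimated correlation). The 4 EIF2AK genes and EIF4EBP2, with 0.10, are among the 7 that rose, but EIF4EBP1 and EIF4EBP3 fell by 0.39 and 0.87. Of 14 TNF receptor superfamily genes 7 fell and 3 rose (median -0.42, adjusted p = 0.0117 by camera, and adjusted p = 0.975 with an estimated correlation). Those that fell include the death receptors TNFRSF10A and TNFRSF10B with -0.87 and -0.68, TNFRSF10D with -0.92 and TNFRSF21 with -1.32. TNFRSF25, with 0.54, is among the 3 that rose. The UTP genes, which overlap the ribosome biogenesis list, had 10 of 11 lower (median -0.54, adjusted p = 0.00709 by camera, and adjusted p = 0.693 with an estimated correlation). The sign of each family's median was the same under TMM, RLE and upper-quartile scaling.

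Implied transcript length, the count divided by the FPKM, is a second readout that the count tests do not use. Among 8429 genes with an FPKM of at least 5 and at least 200 reads in each library, 8 shifted by 0.3 or more on the log2 scale without overlap of the groups, all towards longer transcripts with FIIN-2. The groups did not overlap for 50.6% of the 8429 genes, where chance gives 10%, so small differences between the groups are widespread in this readout and the lack of overlap does not single out the 8. The largest shifts were in DNAH14 (0.74), RGS3 (0.54) and TAF8 (0.47), and the others were KLHL7, ACTR8, METTL8, CLMN and DBT. The median shift over all these genes was 0.0082 in absolute value. With 3 libraries against 3, no exact test of 1 gene can give p under 0.1, and these shifts were not tested further.

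Genes with few reads tended to be higher with FIIN-2. Of 1104 genes with a mean of 10 to 30 reads, the median log2 fold change was 0.31 (95% bootstrap interval over genes 0.25 to 0.36), and of 1021 genes above 3000 reads it was -0.07 (-0.09 to -0.05); without the filter, 211 genes of the first kind rose and 63 fell at least 2-fold. One scaling error per library would shift both kinds alike, but the median of genes with 10 to 100 reads lay 0.31 above that of genes above 1000 (0.27 to 0.34). After GC and length offsets that difference was 0.307 (0.273 to 0.342), which argues against that bias as the whole cause, and background reads added equally per kilobase would give a ratio of 1 between the gains of genes with 30 to 100 and with 10 to 30 reads, where it was 1.78 (1.19 to 2.60). A broad effect of the treatment on weakly expressed genes may remain, as an untested hypothesis, as may other technical differences between the groups that no label records.

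The MTRNR2L genes, nuclear copies of mitochondrial 16S ribosomal RNA, were higher with FIIN-2, with 0.842% to 0.869% of all counts in the DMSO libraries and 1.15% to 1.21% in the FIIN-2 libraries. The 6 with at least 50 reads had log2 fold changes of 0.38 to 0.50, and all 6 were called higher by edgeR. Reads of one source, divided in fixed proportion among the copies, would give one fold change, but the values differed by more than their standard errors (heterogeneity p = 0.0172, chi-square test across genes). That argues against a fixed division as the whole cause. A mixture of shared mitochondrial reads and reads of the copies themselves may still account for the rise, and it was not tested, because mitochondrially encoded genes are not among the genes analysed here.

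Of the 10 ways to split the 6 libraries 3 against 3, 1, the real one, gave as many calls as the 9016 reported, and the highest of the others was 0 in edgeR (49 to 79 genes at an unadjusted p under 0.05). With 10 splits no share under 0.05 can be reached. Each of the other splits also puts libraries of both groups on each side, so the difference between the groups widens the spread. Few calls were likely there in advance, and their lack is no support for the 9016.

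Further hypotheses were set before the data were examined. The hypothesis that blocking the FGF19 and FGFR4 axis raises CYP7A1 within 6 hours needed a higher CYP7A1, which edgeR without the filter called (adjusted p = 0.000732), on 15 reads over the 3 FIIN-2 libraries and none with DMSO; the fits that could test it gave 0.000732 to 0.00823 as adjusted p. FIIN-2 inhibits other FGF receptors too, so the part of FGFR4 was not tested on its own. With a single inhibitor at a single dose, any effect through kinases other than the FGF receptors cannot be told apart either. That the reactive acrylamide of FIIN-2 raises NRF2 targets was left open: 11 of 24 rose and 6 fell, with a median of 0.12 (adjusted p = 0.125 by camera on the edgeR fit), FTL rising by 0.54 and ABCC2 by 1.15. Of 10 aryl hydrocarbon receptor targets 4 rose and 3 fell, with a median of 0.26 but a test that pointed lower (adjusted p = 0.569 by camera), and TIPARP fell by 0.76. Of 36 autophagy and lysosome genes 16 rose and 10 fell, with a median of 0.03 (adjusted p = 0.331 by camera), MAP1LC3B falling by 0.88 and ULK1 rising by 0.49. For these 3 lists a missed threshold had been set down beforehand as evidence against. That was too weak a criterion, since members went both ways and camera often misses a small rise in these libraries: when random tested genes were raised in lists of the same sizes, it called 5.6% to 20.8% of the lists raised by 1.1-fold, 34.6% to 79.4% by 1.2-fold and 95.2% or more by 1.5-fold. Fry called the NRF2 and autophagy lists higher (adjusted p = 3.28e-05 and 0.000865) and the AHR list lower (adjusted p = 0.000593); over all alternatives adjusted p ran to 0.233, 0.645 and 0.635.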
